A study of Rattus norvegicus with 52 samples.

How the data were processed

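Single-cell RNA sequencing was done on 52 DiI-labelled cells cut by laser from aneurysm lesions of 3 rats, and the SMART-Seq Single Cell Plus kit was used for libraries, per the labels' protocols. The deposited table holds whole-number counts per gene symbol and cell, as the values show, with no normalization. The aligner, the counting tool, the genome build, the annotation and any removal of duplicates are not given in the sources used here. The sheet of index sequences deposited with the counts was not used for values. It lists all 52 libraries together, and its header names a stranded mRNA assay while the labels name the SMART-Seq kit, so whether counting used strand is open. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain.

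Each column was assigned to its cell and rat by its title, and 0 columns were left over. No cell was left out of the main values. Totals ran from 1538 to 84848 counts per cell, with a median of 15068. At such depths most genes have 0 to a few counts in a cell, and 1 count in a shallow cell gives a high CPM. No molecular identifiers are recorded, so intervals and limits for 0 counts (3 counts of the total) cover counting error only, not differences between rats. No doublet caller was run, since cells were picked singly. No 2 columns were identical, and the highest correlation between 2 cells was 0.353 across 9494 genes found in at least 5 cells.

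A gene counted as detected at 1 or more counts. Levels were log2(CPM + 1), computed from the deposited counts with the column total as library size. For each of 14 cell type lists and 27 other lists, fixed before the data were examined, the percent of measured members detected per cell and the mean level were averaged within each rat and then over 3 rats. Of 463 list members 441 had a row, and the others were not analysed here. The labels give 1 group, so edgeR's gene-wise test between groups had nothing to compare, and edgeR was used only for TMM scaling. Pairs of lists were compared within cells by a 2-sided exact sign-flip permutation test of the 3 per-rat differences, whose smallest p is 0.25. The planned family had 15 tests and a smallest Benjamini-Hochberg adjusted p of 0.417, each test being an exact permutation. The 12 contrasts at 5 or more counts were recomputed as results of their own after the data were seen, with a smallest adjusted p of 0.333 from the same exact test. No test between lists used single cells as replicates. Binomial intervals over 52 cells and bootstrap intervals over the cells of 1 rat treat cells as independent.

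Shared variable genes were the 500 with the highest residual SD over a lowess trend on the mean in rat 2 and in rat 3. Clusters used 500 variable genes, gene-wise z-scores, 5 principal components and Ward linkage, with 2 to 6 clusters chosen by silhouette. Genes named in the text follow a rule fixed before the data were examined. It took the 25 highest levels outside mitochondrially encoded, ribosomal protein and unnamed features, the 3 most often detected members of each list, 22 fixed genes of interest, the 15 most variable genes of rat 2 and rat 3, and 5 leading genes per cluster. Some genes that the rule takes are not reported here. Others are said to be chosen after their values were seen, or are members of a cell described by its counts.

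Both procedures were tested on simulated counts in which 200 genes were raised in 25 of the 52 cells. With a dispersion of 0.802 from moments, 13% of genes raised 4-fold, 72% of those raised 16-fold and 95.5% of those raised 64-fold were recovered as shared variable genes, among 5196 to 5217 genes tested. With a dispersion of 8, matched on the number of genes tested, recovery was 12%, 25% and 33% among 2087 to 2125 genes. The adjusted Rand index of the clusters with the raised cells was 0.923 and 0.961 at the lower dispersion, for mixed 4-fold and 16-fold changes and for 64-fold changes, and 0.124 and 0.761 at the higher one. Recovery of shared variable genes at the higher dispersion was thus low even for 64-fold changes. The 64-fold size and the matched dispersion were added after the first simulated results were seen. A simulated list contrast of 40 points was recovered as 43.2 ± 7.70 points.

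Alternatives covered the count needed for detection, cells with fewer than 1000 genes, equal weights for cells, thinning to 10181 counts, pseudocounts of 0.1 and 10, a filter on rare members, TMM scaling, each rat left out and the settings of the variable genes and clusters. Thinning kept 39 cells and left out 13. A RefSeq gene table of assembly GRCr8 matched 16686 of 22081 symbols directly and 18269 with synonyms, and was used for 1 check in the closing section. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.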

Results

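The series profiled macrophages taken from arterial aneurysms that had been induced in male Sprague Dawley rats. The model joins the cut left common carotid artery to the right one to make a new bifurcation, and adds salt loading, ligation of a renal artery and a diet with an inhibitor of lysyl oxidase, the enzyme that cross-links collagen and elastin. Nanoparticles carrying the red dye DiI were injected to label phagocytic cells, and single labelled cells were cut from the lesion with a laser. The data comprised 52 single-cell libraries from 3 rats, with 5 cells from rat 1, 23 from rat 2 and 24 from rat 3. All belonged to 1 group, and no control artery was analysed here, so the comparisons below set gene lists against each other within the same cells. The rat was the replicate (n = 3), and with 3 rats the smallest 2-sided exact sign-flip p is 0.25, so no comparison could pass a threshold of 0.05 by this test.

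Libraries were shallow and uneven. The median total was 15068 counts per cell, from 1538 to 84848, and the median number of genes with a count was 2690. Rat 2 was the shallowest, with a median of 11390 counts and 1486 genes, against 18261 counts and 2623 genes in rat 1 and 21841 counts and 3506 genes in rat 3. Of 22081 genes in the table, 3544 had no count in any cell and 9043 were found in 1 to 4 cells. Mitochondrially encoded genes took a median of 0.0882% of counts and ribosomal protein genes 1.06%.

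**Figure D1:**
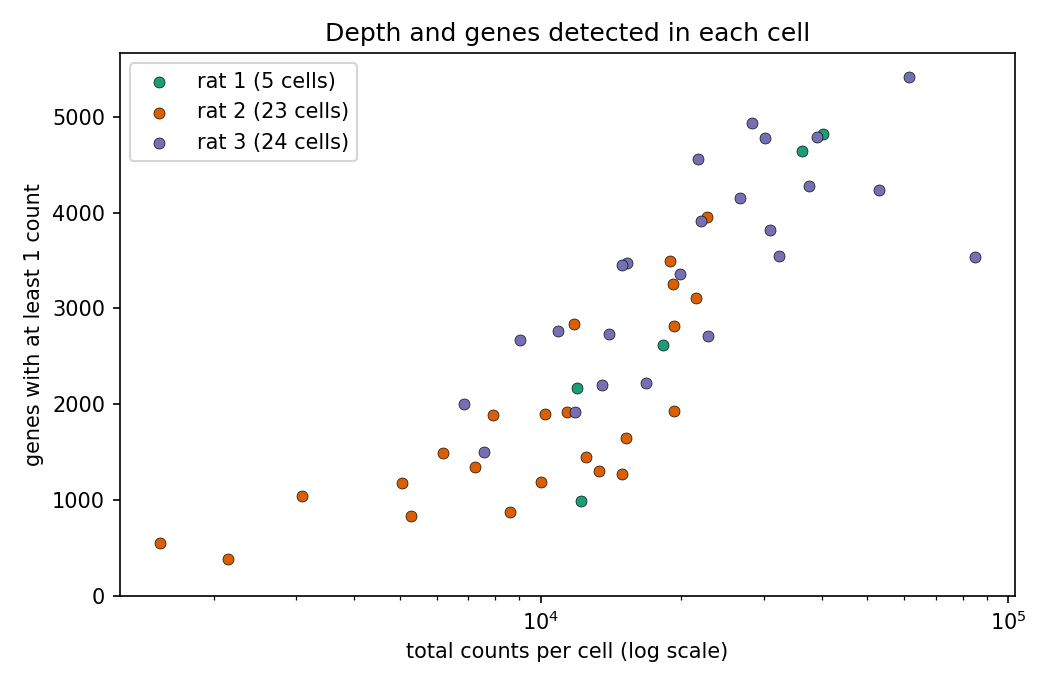
Each point is 1 cell, with its total counts on a log axis and its number of genes with at least 1 count on the vertical axis, coloured by rat. Cells with more counts have more genes, and the cells range from 384 to 5417 genes.

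Among named genes outside the mitochondrially encoded and ribosomal protein genes, the highest levels belonged to a set shared by nearly every cell. The unnamed feature AABR07015057.1, left out of this ranking, was also found in all 52 cells, with up to 43756 counts. It held the most counts of any feature in cells of all 3 rats. Pcdh10, a protocadherin of cell adhesion, was found in all 52 cells at a log2(CPM + 1) level of 15.48 ± 0.55 (SD, n = 3 rats) and took 5.53% of counts. Sdccag8, a centrosomal protein, reached 14.10 ± 1.10 and Csnk2a1, a catalytic subunit of casein kinase, 13.00 ± 0.27, also in all 52 cells. Dnajc27 (13.56 ± 1.31), Tmem170a (12.90 ± 0.92), Rab40b (12.47 ± 1.37), the coactivator Crebbp (12.09 ± 0.63), Xpnpep3 (11.73 ± 0.65), the nucleotide receptor P2ry6 (11.45 ± 0.71), Ube2e3 (11.19 ± 0.57), Rnf225 (11.12 ± 0.69) and the lysosomal membrane protein Lamp1 (11.05 ± 0.32) followed. Polr2d, Mip, Fam32a, Fan1, Acer2, Stk11, Bnip3l, Cpm, Zc3h4, Tcf23, Golga1, Fitm2 and Prdm16 completed the 25 highest, at 9.54 to 10.75. None of these 25 genes belongs to the macrophage list. The table alone does not show that their counts came from transcripts of the named genes. The 52 genes found in at least 50 cells together took 31.2% ± 5.53 (SD, n = 3 rats) of counts, from 13.1% to 60.4% per cell. In rat 3 cell 44 the unnamed feature AABR07015057.1 took 51.6% of counts, and in rat 2 cell 25 Chd4 took 46.4%.

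The first question was whether cells labelled as macrophages carried macrophage transcripts above those of other arterial and blood cells. At 1 or more counts, a cell held 17.5% ± 4.69 (SD, n = 3 rats) of the 21 measured macrophage markers. Over all genes in the table the share was 12.6% ± 3.88 (SD, n = 3 rats). Background sets lay on both sides of the macrophage list. The 35 Hox cluster genes (20.2% ± 7.23) and mitochondrially encoded genes (20.4% ± 7.88) stood above it. Ribosomal protein (15.1% ± 4.78), keratin (6.93% ± 2.96) and sensory receptor genes (2.07% ± 0.877) stood below it (SD, n = 3 rats). Detection at 1 count therefore does not set the macrophage list apart from every background set. Classical markers were sparse. Cd68, a lysosomal glycoprotein of macrophages, was found in 6 of 52 cells (11.5%, exact binomial 95% interval 4.35 to 23.4), Csf1r, the receptor that sustains macrophages, in 12 cells, Lyz2, lysozyme, in 9 cells, the pan-leukocyte gene Ptprc in 6 cells, Aif1 in 2 cells and Cd14 in 1 cell. Fcgr3a, an Fc receptor, was the most frequent member, in 35 cells (67.3%, interval 52.9 to 79.7) with at most 18 counts, followed by the oxidase subunit Cybb and the myeloid transcription factor Spi1 in 16 cells each. Such intervals treat cells as independent and leave out differences between rats.

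Vessel wall and fat cell lists had higher means at this threshold. Smooth muscle markers stood at 25.8% ± 6.67, fibroblast markers at 22.0% ± 7.51, endothelial markers at 21.1% ± 6.17 and adipocyte markers at 21.5% ± 7.24 (SD, n = 3 rats). The macrophage list was 8.37 percentage points below smooth muscle, lower in 3 of 3 rats (value -8.37 ± 8.83, exact p = 0.25, adjusted p = 0.417). The size depended on rat 3, at -3.52 points without it, and was -4.51 points with cells thinned to 1 depth, no longer lower in 3 of 3 rats (exact p = 0.75). It was also below the fibroblast list (-4.52 ± 11.0), the adipocyte list (-4.07 ± 10.4) and the endothelial list (-3.64 ± 6.94) (SD, n = 3 rats). Each of these 3 differences was negative in rat 2 and rat 3 and positive in rat 1, with an exact p of 0.75, and without rat 3 they were 0.789, 1.18 and 0.350 points. With each cell weighted equally they were -8.66, -7.83 and -5.41 points, and the smooth muscle difference was -11.2. The NK cell list, at 20.2% ± 6.83, rested on Prf1, the pore-forming protein of cytotoxic lymphocytes, which was found in 40 cells, and the macrophage list lay -2.71 ± 3.53 points from it (exact p = 0.5). The common members of the vessel wall lists were Mylk (39 cells), Acta2 (35), Myocd (22), Kdr (36), Nos3 (28), Vwf (16), Col1a1 (33), Fbln1 (33) and Col3a1 (13).

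Lists of most other blood cells had lower means. The macrophage list exceeded the platelet list by 14.6 ± 7.11 points, the B cell list by 11.8 ± 2.25, the neutrophil list by 10.5 ± 2.09, the T cell list by 10.4 ± 4.99, the erythroid list by 8.20 ± 6.72 and the mast cell list by 7.71 ± 1.22, each in 3 of 3 rats with an exact p of 0.25 and an adjusted p of 0.417 over 15 tests. Some of these rested on 1 cell: without cell 4 of rat 1 the mast cell difference was 4.25 points, and without cell 39 of rat 3 the erythroid difference was 7.59, each no longer in 3 of 3 rats (exact p = 0.5). Without cell 4 of rat 1 the B cell and erythroid differences were 7.83 and 5.42 points, and without rat 1 the erythroid difference was 5.15. The macrophage list exceeded the Schwann and neuronal list by 2.76 ± 3.50 points in 2 of 3 rats (exact p = 0.5), and by 1.03 without rat 2. Dendritic cell markers stood at 7.24% ± 3.31.

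Requiring 5 counts turned the direction against the vessel wall. At that threshold a cell held 7.44% ± 4.28 of the macrophage markers, against 4.43% ± 4.05 of smooth muscle, 5.58% ± 1.40 of fibroblast and 2.39% ± 1.57 of endothelial markers (SD, n = 3 rats). Over all genes the share was 1.99% ± 0.785 (SD, n = 3 rats). Among background sets, Hox cluster (0.980%), keratin (0.917%) and sensory receptor genes (0.132%) stood below the macrophage list. Ribosomal protein (7.99%) and mitochondrially encoded genes (12.7%) stood above it. The macrophage list then exceeded the endothelial list by 5.05 ± 5.07 points in 3 of 3 rats (exact p = 0.25), the smooth muscle list by 3.01 ± 7.45 in 2 of 3 rats (exact p = 0.75), and the fibroblast list by 1.86 ± 5.67 in 1 of 3 rats (exact p = 1). Among 10000 random lists of the same size drawn from all genes, the macrophage value lay at the 90.9 percentile for 1 count and the 99.2 percentile for 5 counts. Smooth muscle lay at 99.0 and 89.0, fibroblast at 95.6 and 93.1 and endothelial at 94.4 and 72.8. The random lists included the 3544 genes with no count in any cell. At 5 counts the housekeeping list lay at 99.8, the lipid-associated list at 98.8 and the growth factor list at 98.1. A high percentile is therefore not particular to macrophage markers. The sizes of the leads over these 3 lists depended on 1 cell: without cell 4 of rat 1 the differences were 1.96 points (endothelial), -0.0753 (smooth muscle) and -0.581 (fibroblast). The endothelial lead was 2.29 points without rat 1, and 4.64 without cell 39 of rat 3, no longer in 3 of 3 rats (exact p = 0.5).

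**Figure D2:**
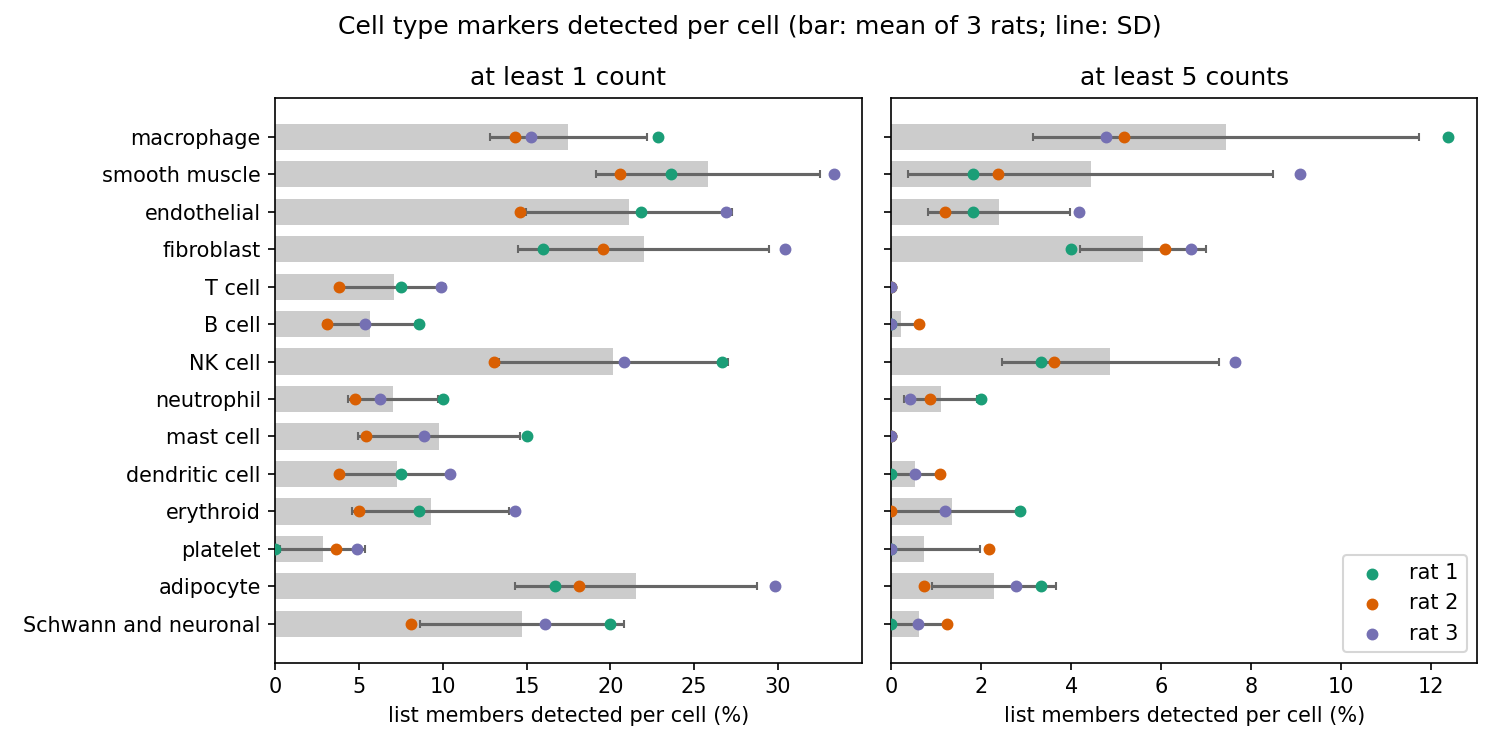
Percent of each cell type's markers detected per cell, with at least 1 count on the left and at least 5 counts on the right; bars are means of 3 rats, lines the SD and points the rats. The macrophage bar is at 17.5% on the left, below smooth muscle at 25.8%, and at 7.44% on the right, above smooth muscle at 4.43%.

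Abundant macrophage transcripts were gathered in few cells. No macrophage marker reached 5 counts in 25 cells, and 7 cells had 3 or more, a selection made after the values were seen. Rat 1 cell 4 had 10 such markers, with 236 Lyz2, 68 Lgals3 and 33 Cd68 counts beside 965 of Apoe, which is on the lipid-associated list. Rat 3 cell 39 had 8, with 579 C1qa, 330 C1qb and 192 Csf1r counts beside 3411 of Apoe. Rat 2 cell 7 had 6, with 252 C1qa and 95 Cd68 counts beside 219 of Gpnmb. These cells also lacked some members of the macrophage list. Rat 1 cell 4 had 0 C1qa and 0 Csf1r counts, and rat 2 cell 7 had 0 Lyz2 and 0 Csf1r counts. Rat 3 cell 39 had 0 Cd68, 0 Tyrobp and 0 Fcer1g counts. Apoe is a lipid carrier made by macrophages, the C1q genes encode the first complement component, and Gpnmb marks lipid-loaded macrophages.

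**Figure D3:**
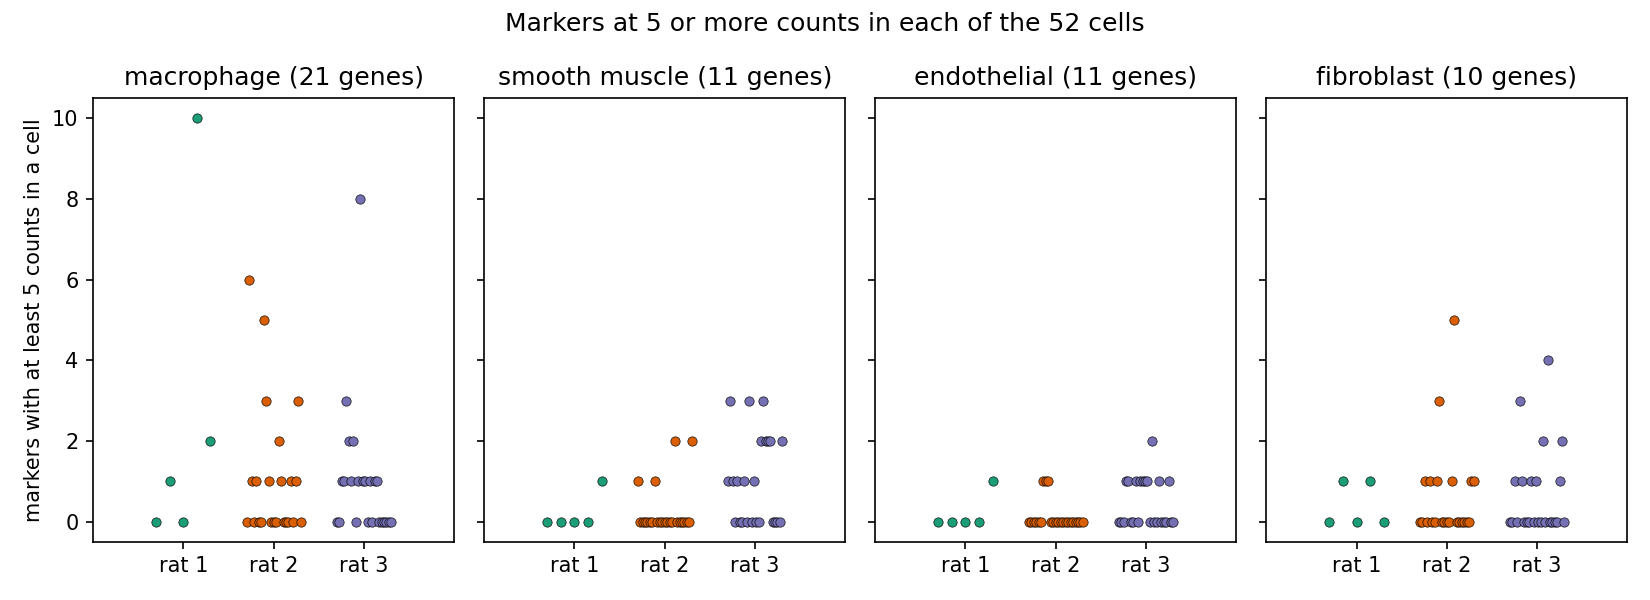
Each point is 1 of the 52 cells, and the vertical axis counts the markers of a list with at least 5 counts in it. A few cells reach 5 to 10 macrophage markers, while the smooth muscle list reaches 3, the endothelial list 2 and the fibroblast list 5.

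The second question was how classical and alternative activation genes compared. The proinflammatory list had a mean log2 level of 0.40 ± 0.13 and the alternative list 1.33 ± 0.35 (SD, n = 3 rats), a difference of -0.93 ± 0.25, lower in 3 of 3 rats (exact p = 0.25, adjusted p = 0.417), and -0.51 with a pseudocount of 10. No member of the proinflammatory list reached 5 counts in any cell. Tnf was found in 0 of 52 cells, which allows a share of up to 5.77% of cells with a Tnf count and sets no limit on cells that express it, Il6 in 1 cell, Il1b in 2, Nos2, the inducible nitric oxide synthase, in 5, and Ptgs2, the inducible cyclooxygenase, in 18 with at most 3 counts. Of the alternative list, the mannose receptor Mrc1 was found in 33 cells, Klf4 in 30 and Il4r in 27, with Tgfb1 in 15, Cd163 in 4 and Arg1 in 3. Counts this low limit what can be said of any single gene. Levels of background sets ran from 0.13 (sensory receptor) to 1.77 (mitochondrially encoded), with keratin at 0.44, Hox cluster at 1.24 and ribosomal protein at 1.26. Both lists were averaged over all 52 cells, of which 25 had no macrophage marker at 5 or more counts. The difference therefore does not by itself show an activation state of macrophages.

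Matrix-degrading enzymes were compared with their inhibitors. The protease list stood at 0.82 ± 0.25 and the inhibitor list at 1.09 ± 0.12 on the log2 scale (SD, n = 3 rats), a difference of -0.27 ± 0.14, lower in 3 of 3 rats (exact p = 0.25). The size depended on the settings, at -0.89 with members found in at least 3 cells, -0.44 with a pseudocount of 0.1 and -0.11 with a pseudocount of 10, the last no longer lower in 3 of 3 rats (exact p = 0.5). Ctsb, a lysosomal cysteine protease, was found in 10 cells with up to 807 counts, Mmp2 in 10 and Mmp9, gelatinases that degrade collagen, in 7. Among inhibitors Cst3, a secreted inhibitor of cysteine proteases, was found in 10 cells.

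Markers of resident macrophages stood at 1.90 ± 0.26 and those of recruited monocytes at 1.38 ± 0.94 on the log2 scale (SD, n = 3 rats). The difference of -0.51 ± 1.03 was negative in rat 2 (-1.12) and rat 3 (-1.10) and positive in rat 1 (0.68), with an exact p of 0.5. It was -1.11 without rat 1, -0.21 without rat 2 and -0.22 without rat 3. Stab1, a scavenger receptor, was found in 40 cells, Igf1 in 34 and the hyaluronan receptor Lyve1 in 31. Fn1 was found in 18 cells, Vcan in 15 and Itgal in 11. Ccr2, the receptor that guides monocytes to tissue, was not analysed here.

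Among the remaining lists, growth factor genes were the most often detected at 1 or more counts, at 36.0% ± 9.20 of members per cell (SD, n = 3 rats), with Tgfb2 and Pdgfa in 42 cells each and Vegfa in 36. At 5 or more counts they stood at 7.48%, below the housekeeping (15.5%), iron handling (8.49%) and lipid-associated (7.80%) lists. The lipid-associated list stood at 20.2% ± 8.73, with Abca1 in 26 cells and Apoe in 20, the phagocytosis and scavenger receptor list at 19.3% ± 5.20 and the iron handling list at 19.0% ± 6.66, with Fth1 in 16 cells and Ftl1 in 15. Salt and mineralocorticoid genes stood at 22.4% ± 5.32, led by the tonicity-responsive factor Nfat5 in 47 cells. The sphingosine-1-phosphate list stood at 16.0% ± 7.32, with the receptor S1pr1 in 19 cells, and the prostaglandin and leukotriene list at 11.2% ± 4.27, with the prostaglandin E receptor Ptger2 in 4. NF-kB and TLR genes stood at 13.0% ± 5.83, with Nfkbia in 21 cells and Nfkb1 in 5. Chemokines stood at 11.0% ± 2.86, led by Cxcl12 in 22 cells, with Ccl2 in 4, and chemokine receptors at 7.00% ± 4.88. Spp1 was found in 5 cells.

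Mean profiles of the rats were compared across 18537 genes, which are not independent replicates. Pearson's r was 0.865 between rat 2 and rat 3, 0.716 between rat 1 and rat 2 and 0.700 between rat 1 and rat 3, with Spearman's rho of 0.596, 0.444 and 0.462. Among 2375 genes found in at least 5 cells of both rat 2 and rat 3, 263 were in the 500 most variable of each, against 105 for independent lists. That formula is too low a reference here: in simulated tables with no gene changed and a dispersion matched on the number of genes tested, 191 genes were shared on average, from 178 to 204 in 20 runs, with 2059 genes tested and 121 for independent lists. At the dispersion from moments the average was 119.8, from 104 to 141, but with 5188 genes tested and 48.2 for independent lists, so it is not a lower reference for 263. Among the genes ranked highest in both rats, Acta1, Apoe, Col1a1 and Tmsb4x stood beside Dnajc27, Polr2d, Gtf3c2, Slc18a1, Spag11a, Nbas and the unnamed features AABR07015081.2 and LOC108348108.

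Clustering put the cells into 5 clusters with a mean silhouette of 0.279. Simulated tables with no gene changed, 1 per dispersion, also gave clusters. There were 4 with a silhouette of 0.172 at the matched dispersion. There were 2 with a silhouette of 0.566 at the dispersion of 0.802 from moments, which was not matched on the number of genes tested. The value of 0.279 lay between them, and 1 table each gives no spread. The silhouette therefore cannot tell whether these clusters differ from chance. Cluster 1 (24 cells) was led by Ac1576, Synj2, Unc80, AC109048.1 and Lrpap1, and cluster 2 (12 cells) by Eif4e3, Prdm10, Coa4, Nsrp1 and Cers3. Cluster 3 (7 cells, from 3 rats) was led by Tmsb4x, B2m, Vim, Apoe and Rplp1, and cluster 5 (4 cells, all of rat 2) by Fth1, Ctsb, Tmsb4x, Apoe and Rps28. Cluster 4 (5 cells) had Acta1, Hist2h4a, AABR07042903.1 and LOC100912489 among its leading genes. Acta1 and Hist2h4a belong to families with near-identical copies or pseudogenes, so their counts are uncertain. The median number of macrophage markers at 5 or more counts was 3 in clusters 3 and 5 and 0 in clusters 1, 2 and 4. The median share of ribosomal protein genes moved with it, at 4.27% and 4.98% in clusters 3 and 5 against 0.334%, 0.698% and 1.23% in clusters 1, 2 and 4, and cluster 3 was the deepest, with a median of 36177 counts and 4238 genes. No cluster was given a cell type name.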

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

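Cells of rat 1, the only rat with 4 to 10 cells, were checked for a cell far from the others, in 25 quantities over 5 cells, and 8 stood apart. Chance flags about 1 in 20 groups, and a quantity that is 0 in 4 cells flags any count in the other, so 7 of these carry little weight. Rat 1 cell 4 had 10 macrophage markers at 5 or more counts, against 2 in the next cell. It also had 1 NK cell marker at 5 or more counts, against 0. Rat 1 cell 5 had 1 smooth muscle, 1 endothelial, 1 neutrophil and 1 adipocyte marker at 5 or more counts and 3 B cell markers at 1 or more, against 0 in the others. Rat 1 cell 1 had 1 erythroid marker at 5 or more counts, against 0.

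The gathering of macrophage markers in few cells was weighed against 2 technical explanations, with both tests chosen after the result was seen. The tables argue against library depth: the variance over cells of the number of macrophage markers at 5 or more counts was 4.04, above the range of 1.04 to 2.23 in draws weighted by each cell's number of genes at 5 or more counts. The fibroblast list (1.16 against 0.429 to 0.814) and the smooth muscle list (0.856 against 0.395 to 0.818) also exceeded their draws, with 4 and 3 cells holding 3 or more markers, so gathering beyond depth is not particular to macrophage markers. Spill-over from rat 3 cell 39, the library with the most Apoe, would carry its C1qa along. Of 9 other libraries with 50 or more Apoe counts, 8 held 0 C1qa where at least 11.9 were predicted, which argues against spill-over from that cell. Spill-over from other libraries, such as rat 1 cell 4 with 965 Apoe and 0 C1qa counts, was not tested. Cells that failed to yield RNA, or labelled cells of another kind, may remain as explanations and stay open. The 7 cells with 3 or more macrophage markers had 1.50% to 13.0% of counts in ribosomal protein genes, against a median of 1.06% over all 52 cells, a comparison made after the result was seen. Rat 1 cell 4, with the most markers, had the lowest of these shares. Other cells also had high shares: 6.13% in rat 3 cell 43 and 4.20% in rat 2 cell 20, with 1 such marker each, and 4.02% in rat 2 cell 23, with 0. All 7 shares thus lay above the median, although high shares were not limited to these cells. No biological explanation was tested, since the labels give 1 group.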

How the results depend on the processing

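The 10-count threshold, the 5-count contrasts as results of their own and the runs without single cells were chosen after seeing the data. The exact sign-flip test cannot go below 0.25 with 3 rats, so directions and sizes are compared. Of 15 planned contrasts 10 kept their direction under each alternative run. The direction of the macrophage list against 5 lists depended on the count needed for detection. At 5 or more counts it exceeded smooth muscle by 3.01, endothelial by 5.05, fibroblast by 1.86, NK cell by 2.57 and adipocyte by 5.16 points, and at 10 or more by 2.04, 4.05, 0.933, 2.53 and 3.89. Thinned to 1 depth it exceeded endothelial by 0.202 points and Schwann and neuronal by 7.95, the latter in 3 of 3 rats, and the differences from adipocyte, fibroblast and NK cell were -0.275, -2.02 and -1.39. With each rat left out in turn the differences at 1 count ran from -12.2 to -3.52 (smooth muscle, and -4.51 thinned to 1 depth). They ran from -5.98 to 0.350 (endothelial), -10.2 to 0.789 (fibroblast) and -9.21 to 1.18 (adipocyte), these 3 being positive without rat 3, and from -4.68 to -1.28 (NK cell) and 1.03 to 4.53 (Schwann and neuronal). At 5 counts they ran from -0.762 to 6.68 (smooth muscle), -1.41 to 3.73 (fibroblast) and -0.662 to 5.30 (NK cell), negative without rat 1. Without cell 4 of rat 1 those at 5 counts were -0.0753 (smooth muscle), -0.581 (fibroblast), 1.96 (endothelial), 1.95 (adipocyte), 0.749 (NK cell), 4.50 (T cell), 4.30 (B cell), 3.24 (neutrophil), 4.50 (mast cell), 2.92 (erythroid), 3.78 (platelet) and 3.89 (Schwann and neuronal), with the erythroid and adipocyte differences no longer in 3 of 3 rats. With each cell weighted equally the differences at 5 counts were -0.476 (fibroblast), 0.258 (smooth muscle), 3.06 (endothelial) and 0.229 (NK cell). At 1 count the differences without that cell were -6.44 (endothelial), -8.27 (fibroblast), -7.33 (adipocyte), -5.41 (NK cell), 7.83 (B cell), 4.25 (mast cell), 5.42 (erythroid) and 1.41 (Schwann and neuronal). The causes were not tested. The 3 level contrasts kept their direction with other pseudocounts, TMM scaling and the filter on rare members, but sizes moved. Proteases against inhibitors ran from -0.89 with that filter to -0.11 with a pseudocount of 10, proinflammatory against alternative was -0.51 with a pseudocount of 10, and recruited against resident was -0.27 there, -0.94 with each cell weighted equally and -1.11 to -0.21 with each rat left out.

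Requiring 5 counts lowers detection by construction, and the median number of genes per cell fell to 310.5. List detection was then 7.44% (macrophage), 4.43% (smooth muscle), 2.39% (endothelial), 5.58% (fibroblast), 0% (T cell, mast cell and proinflammatory), 0.207% (B cell), 4.87% (NK cell), 1.10% (neutrophil), 0.536% (dendritic cell), 1.35% (erythroid), 2.28% (adipocyte), 0.612% (Schwann and neuronal), 4.03% (alternative), 4.58% (matrix protease), 4.13% (protease inhibitor), 6.07% (recruited monocyte), 7.62% (resident macrophage), 1.56% (chemokine), 0.315% (chemokine receptor), 1.66% (NF-kB and TLR), 1.47% (inflammasome), 0.681% (prostaglandin and leukotriene), 1.23% (sphingosine-1-phosphate), 7.80% (lipid-associated), 3.25% (MHC class II), 2.55% (complement), 5.62% (phagocytosis and scavenger receptor), 4.27% (oxidative burst and antioxidant), 7.48% (growth factor), 3.55% (interferon response), 5.41% (hypoxia and glycolysis), 3.48% (immediate early and stress), 0.437% (proliferation), 8.49% (iron handling), 2.73% (mechanosensing), 4.75% (salt and mineralocorticoid), 1.72% (apoptosis and survival) and 15.5% (housekeeping). The correlation of rat 1 and rat 2 was 0.843 over genes in at least 5 cells of each. Rat 1 has 5 cells, so this filter kept only genes found in all of its cells. Shared variable genes numbered 106 of the top 200, against 16.8 for independent lists, and 572 of the top 1000, against 421. Independent lists were too low a reference for the top 500, and no simulated reference was made for these 2 settings. With genes in at least 10 cells of each rat, 362 were shared against 349 for independent lists. The number of clusters ran from 4 to 6, and membership changed: the adjusted Rand index with the reported clusters was 0.289 after centring within rats and 0.317 with 1000 variable genes. No paired analysis was possible because the labels give 1 group, so that no groups of samples could be paired. The lists were compared within rats.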

Other observations

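Of the tests in this part, the comparison by depth was set before its result was seen, and the others after. Housekeeping genes were themselves sparse: a cell held 27.1% ± 7.14 (SD, n = 3 rats) of 9 measured members, with Tpt1 in 25 cells and Actb in 22. Interferon response genes stood at 14.3% ± 2.27, with Oasl in 45 cells, Bst2 in 33 and Mx2 in 5. Immediate early and stress genes stood at 24.6% ± 7.50, with Jund in 34 cells, Egr1 in 25 and Fos in 16. Hypoxia and glycolysis genes stood at 19.3% ± 6.49, with Egln3 in 31 cells, Hk2 in 24 and Slc2a1 in 11. Apoptosis and survival genes stood at 20.2% ± 6.40, and mechanosensing genes at 20.2% ± 7.69, with Klf4 in 30 cells and the channels Piezo1 in 16 and Piezo2 in 15. Oxidative burst and antioxidant genes stood at 14.2% ± 6.65, with Cybb in 16 cells and Ncf1 in 14. Proliferation genes stood at 11.2% ± 3.33, with Birc5 in 18 cells. MHC class II genes stood at 8.02% ± 1.75, with Cd74 and RT1-Da in 8 cells each, complement genes at 8.01% ± 2.22, with C5ar1 in 10, and inflammasome genes at 6.31% ± 3.60, with P2rx7 in 9. Over all genes the share was 12.6% ± 3.88 (SD, n = 3 rats). The interferon response, oxidative burst and proliferation shares lay near it, and the MHC class II, complement and inflammasome shares below it.

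Collagen stood beside Apoe and Lyz2 counts in some cells, chosen after their values were seen. Rat 2 cell 14 had 220 Apoe, 23 Lyz2, 356 Col1a1 and 215 Col3a1 counts, and rat 3 cell 33 had 84 Apoe, 5 Lyz2, 397 Col1a1 and 304 Col3a1 counts. Both had 0 Cd68, C1qa, C1qb and C1qc counts. By contrast rat 3 cell 39 had 3411 Apoe with 2 Col1a1 and 0 Col3a1 counts. Of the smooth muscle markers Acta2 reached 5 counts in 12 cells, Actg2 in 9 and Mylk in 6, while Tagln reached at most 2 counts in any cell. Ribosomal protein genes made up 15 of the 263 shared variable genes from 17 that were tested, against 1.88 for the same share of all tested genes.

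Low detection of macrophage markers beside vessel wall markers was weighed against 3 explanations. Capture of smooth muscle cells instead stays open: 0 of 52 cells had 3 of the contractile genes Acta2, Tagln, Myl9, Tpm2, Myh11 and Cnn1 at 5 or more counts. The bound first written against it, at most 1 such cell, was met, but Actb itself reached 5 counts in only 13 cells, so absence of such genes excludes nothing. The condition that Actb reach 5 counts in at least 26 cells was added after both values were seen. Acta2 was found in 35 cells, and 3 cells of rat 3 had 3 markers of the smooth muscle list at 5 or more counts. Shallow libraries could not be told apart from other causes: the macrophage list minus the mean of 3 vessel wall lists was 3.68 points higher in the deeper cells on average, but 16.0 and 2.61 points higher in rat 1 and rat 2 and -7.54 points in rat 3. An even background of genomic DNA also stays open. Sensory receptor genes were detected 0.345 times as often as other protein-coding genes of the same span, but only 25 such genes were found, and the 95% bootstrap interval over genes ran from 0.133 to 1.60. Reads lost between near-identical receptor genes may lower that ratio too. No biological explanation was tested.

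The genes shared by nearly every cell were weighed against 1 explanation, a fixed number of molecules added to each reaction, which may be pictured as a contaminant. Their summed counts were predicted not to rise with the rest of the library. The slope of log counts on log counts was 0.808 in rat 2 (95% bootstrap interval 0.629 to 0.943) and 0.940 in rat 3 (0.622 to 1.26). A slope above 0.5 had been set as the bound against the explanation, but that bound was wrong, since sequencing depth scales both sums and gives slopes up to 1 even with fixed molecules. The explanation therefore cannot be told apart from others with these counts, and reads from repeats or genomic DNA at these genes were not tested. No biological explanation was tested.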
